A study of Homo sapiens with 4 samples.

How the data were processed

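The series holds 4 microarrays of 2 colours, Agilent Human 1A version 2, hybridised with RNA of primary human bronchial epithelial cells. These cells line the large airways and were grown as monolayers without serum, per the labels' protocols. On 2 arrays, RNA of cells given the double-stranded RNA (dsRNA) poly I:C at 1 µg/ml for 2 h met RNA of untreated cells. On the other 2, RNA of cells infected with respiratory syncytial virus (RSV) at 2.5 plaque-forming units per cell for 24 h met RNA of mock-infected cells. What those received is not given in the sources used here. The groups and numbers of the arrays come from the labels. Total RNA was amplified to labelled cRNA, per the labels' protocols.

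The deposited scanner tables give, for each spot, the mean intensity and the median local background intensity in green (Cy3) and red (Cy5), per the file headers. They also hold the processed intensity and the log10 ratio of red over green after background subtraction, spatial detrending and LOWESS dye normalization on rank-consistent probes, all set by the authors' Feature Extraction run, per the file headers. A p-value of each log10 ratio from the error model of that software within 1 array is deposited as well, per the file headers. The file headers name Feature Extraction 7.5.1 for both dsRNA arrays and 9.1.3.1 for both RSV arrays. The submitters' processing notes name 9.5 and 9.1, and the series text 7.5 and 9.1. The software version therefore goes with the comparison, and values of dsRNA and RSV are set side by side only as ratios formed within each array. A deposited series matrix holds 20158 linear ratios per array, by the authors, with scale, centring and direction unstated. Set against the scanner values, it ran as treated over control on all 4 arrays (r of 0.935 to 0.997 with the turned log ratio), with median ratios of 0.995, 0.982, 1.02 and 1.03. The matrix was used as an alternative source of values. The filter behind its empty cells is not given in the sources used here.

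The direction of each ratio was taken from the dye recorded for each channel. That field puts treated RNA in Cy5 on the first array of each pair and in Cy3 on the second. On the second array of each pair, the text of the labelling protocol names the opposite dyes. The series text says that dyes were exchanged, and the dye field was used. With it, 46 genes of the dsRNA pair passed 2-fold on both arrays with the same sign and 0 with opposite signs, and in the RSV pair 1119 and 1. Between the arrays of a pair, r over genes was 0.97 for RSV and 0.19 for dsRNA, where most genes deviated little and followed the dye.

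Background was corrected with normexp (offset 50) on mean signal and median background, and each array was normalized by loess on its log2 ratios, with limma 3.58.1 in R 4.3.3. Each array has 22153 spots, of which 1080 are controls. Controls had weight 0 in the loess fit, as had spots marked as outliers (2, 23, 5 and 7 per array). Saturated spots were kept, and the fold of a gene saturated in 1 channel on both arrays is a bound, which holds for 5 called genes, all after RSV. Spots of 1 probe were averaged, which concerned 100 probes with 10 spots each, and the sign of the array with treated RNA in Cy3 was turned. Later steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and, for plots, matplotlib 3.10.9.

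Of 20173 probes, 16433 were named through their RefSeq accession in a table of GRCh38.p14 genes, 1058 by current symbol and 456 by an older symbol. Another 385 kept the name in the file, and 1841 had no gene name and were left out of all gene counts. Names were taken from the RSV arrays' annotation, the newer of those in the files. A further 45 probes were left out because they match Y-linked genes, XIST or TSIX, which are not reported for human samples. This left 16510 genes, of which 1666 had several probes and were represented by the probe brightest over all 4 arrays. Where a second probe of a gene given by value gave no call, or the mean over probes moved the value by over 1.5 times, this is said where the gene is first given. Signals were well above background for 88.9 to 99.7% of spots per channel and array, and 2 to 72 spots per channel and array were saturated.

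No test across replicates was made. Nothing in the labels says that the arrays of a pair came from separate cultures, so a pair counts as a technical repeat of 1 sample per group. In place of a test, a gene was called higher (lower) when its ratio of treated over control was at least 2-fold up (down) on both arrays, and it was well above background in at least 1 channel on both. Log2 ratios are means of the pair, and the value after ± is the distance of either array from that mean, which covers technical error alone. A fold is 2 to the power of the mean log2 ratio. A gene not well above background in the control channel on both arrays has a bound, taken after loess and Aquantile scaling. The offset of 50 draws ratios of dim probes toward 0, so folds of weakly expressed genes are understated.

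The normalization and the 2-fold rule were tested on simulated pairs of 20173 probes, with known changes in 20 probes per fold size and direction. The changed probes were drawn without the dimmest ones. Neither the detection rule nor the choice of 1 probe per gene was applied, so the shares below may be too high for dim genes. For the dsRNA pair, 60% of 3-fold and 100% of 4-fold higher probes were called, and 65% and 90% of lower ones. For the RSV pair the shares were 65% and 95% for higher, 55% and 90% for lower probes. Of true 2-fold changes, at most 5% were called in either pair. None of 19973 unchanged probes was called in either pair (0). Their simulated noise was only that between repeat spots of 1 array (SD 0.05 to 0.08), far below the threshold. A call was therefore all but impossible, and the 0 gives no rate of false calls for these arrays.

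The genes named follow a rule fixed before the data were examined. It takes the 12 highest and 6 lowest called genes per comparison, and the 2 called members of each gene list with the largest absolute ratio. Between comparisons it takes the 6 genes called in the same direction in both with the largest smaller ratio, up to 6 called in opposite directions, and the 6 largest differences each way. IFNB1, IFIH1, RIGI, TLR3 and CXCL8 are given whatever their values. Other genes were named after their values were seen, and this is said where they appear. The result of 1 gene that the rule takes is not reported here. The 22 gene lists were also fixed beforehand, with 448 entries, of which 435 are on the array. A list's median was set against 10000 random lists of the same size, matched on mean brightness in 20 bins. This percentile describes these arrays and is no test across samples. The overlap of calls was set beside the overlap of independent lists, the product of both counts over the genes measured in both, and beside 10000 random lists matched the same way.

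Alternatives were normexp with offset 0, no background correction, Agilent's own log ratio, median centring in place of loess, and the series matrix. Others were no filter on detection, detection in both channels, thresholds of 1.5-fold and 3-fold, and Agilent's p under 0.01 on both arrays in addition. The last were the mean over a gene's probes, leaving out saturated spots, and each array of a pair alone.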

Results

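The study set the response of airway epithelium to synthetic dsRNA beside its response to infection with RSV, a negative-strand RNA virus of the respiratory tract. Primary human bronchial epithelial cells had received poly I:C, a dsRNA that mimics viral replication products, at 1 µg/ml for 2 h. Cells of the same kind were infected with RSV at 2.5 plaque-forming units per cell for 24 h. RNA of treated cells was compared with RNA of untreated cells, and RNA of infected cells with RNA of mock-infected cells, each on 2 arrays with exchanged dyes. What the mock-infected cells received is not given in the sources used here, so RSV ratios hold any effect of that too. Of 16510 named genes on the array, 15598 were measured in the dsRNA comparison and 15901 in the RSV comparison. Each group is 1 sample, so no difference has a replicate check and no p-value is given. The 2 arrays per comparison limit the precision, and ± values are the technical deviation of either array from the pair's mean.

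After 2 h of dsRNA, 46 genes were higher by at least 2-fold on both arrays and 0 were lower. IFIT2, an interferon-induced inhibitor of viral translation, had the highest ratio, 37.9-fold (log2 ratio 5.24 ± 0.05). CXCL8, the neutrophil chemokine interleukin-8, was 15.1-fold higher (3.92 ± 0.07) and IFIT1, a sensor of viral RNA ends, 12.04-fold (3.59 ± 0.07). TNFAIP3, the ubiquitin-editing brake on NF-kB also called A20, was 10.7-fold higher (3.42 ± 0.20), and the soluble pattern recognition molecule PTX3 was 10.1-fold higher (3.34 ± 0.11). IFNB1, encoding interferon beta, was 3.27-fold higher (1.71 ± 0.10).

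**Figure D1:**
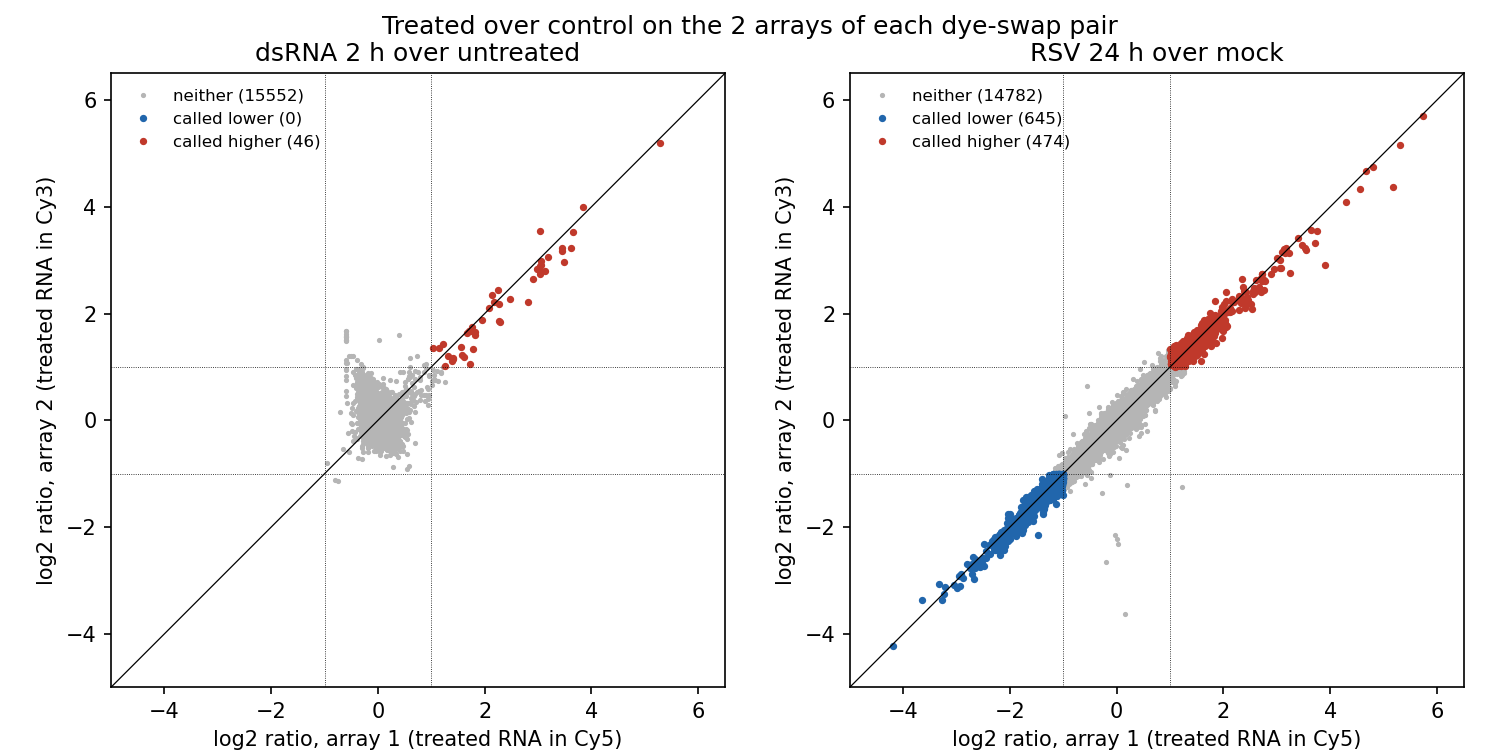
Log2 ratio of treated over control for each measured gene on array 1 (horizontal, treated RNA in Cy5) and array 2 (vertical, treated RNA in Cy3) of the dsRNA pair (left) and the RSV pair (right), with dotted lines at the 2-fold threshold and the diagonal drawn. The 46 genes higher after dsRNA lie along the diagonal while the other genes do not, whereas after RSV genes follow the diagonal in both directions. The vertical row of grey points on the left is made mostly of bright spots near the scanner's ceiling.

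Of 19 measured chemokines, 8 were higher and 0 lower, with a list median of 0.45. CXCL3 was 9.97-fold higher (3.32 ± 0.14), CCL20, which attracts dendritic cells and Th17 cells, 9.80-fold (3.29 ± 0.26), CXCL1 8.73-fold (3.13 ± 0.06) and CXCL11, a ligand of CXCR3, 7.90-fold (2.98 ± 0.07). Of 25 cytokines and growth factors of epithelial inflammation, 8 were higher (median 0.29), led by IL6 at 7.57-fold (2.92 ± 0.12) and LTB, encoding lymphotoxin beta, at 4.59-fold (2.20 ± 0.02). Of 24 NF-kB targets and feedback regulators, 7 were higher (median 0.72), among them TNFAIP2 at 9.32-fold (3.22 ± 0.26, second probe 0.10 but not detected) and NFKBIA, the inhibitor IkB alpha, at 7.80-fold (2.96 ± 0.07). Of 33 immediate-early genes, 3 were higher (median 0.20), with ATF3 at 4.69-fold (2.23 ± 0.05) and the phosphatase gene DUSP1 at 3.33-fold (1.73 ± 0.09). The medians of these 4 lists lay above those of all 10000 random lists matched on brightness.

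Few members of the antiviral lists were called at 2 h. Of 55 interferon-stimulated genes, 5 were higher: IFIT2, IFIT1, IFIT3 at 8.08-fold (3.01 ± 0.03), ISG15 at 5.08-fold (2.34 ± 0.10) and, named after its value was seen, OASL (1.64 ± 0.02). The median of that list was 0.04, above 99.99% of random lists. IFNB1 was the 1 called gene among 13 type I and III interferons (median 0.02), of which 5 had positive and 1 negative ratios on both arrays. The type III genes, named after their values were seen, were positive but uncalled: IFNL2 at 0.94 ± 0.20, IFNL3 at 0.80 ± 0.01 and IFNL1 at 0.43 ± 0.02. RIGI, the cytosolic sensor RIG-I, was 2.42-fold higher (1.28 ± 0.12) and the 1 called among 12 viral RNA sensors and adaptors (median 0.10, above all random lists). The related sensor gene IFIH1 (MDA5) had 0.68 ± 0.21 and the endosomal dsRNA receptor gene TLR3 -0.01 ± 0.03, both uncalled. The transcription factor gene IRF1 was 2.51-fold higher (1.33 ± 0.10), the 1 called among 16 interferon receptors and JAK-STAT regulators. That list's median of 0.12 lay above all random lists, but was 0.04 with median centring. Of 20 cell death genes, PMAIP1, encoding the BH3-only protein NOXA, was the 1 called, at 7.78-fold (2.96 ± 0.17), with a list median of 0.05 (above 98.56% of random lists) that became -0.02 with median centring.

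No member was called in the other lists (0). Of 35 cell cycle genes (median -0.05, above 0.1% of random lists), 10 had negative and 1 positive ratios on both arrays. Of 20 cholesterol synthesis genes (median -0.08, above 0.02% of random lists), 7 had negative and 1 positive ratios on both. The medians were -0.03 for 17 antioxidant genes and -0.03 for 11 heat shock proteins, both inside the central 95%. They were 0.05 for 20 antigen presentation genes and 0.04 for 19 genes of the unfolded protein and integrated stress responses. For 9 squamous differentiation genes the median was 0.13 (above 99.14% of random lists). Each of these medians was below 0 with median centring. The 8 airway basal cell markers had a median of 0.01 and the 16 epithelial junction genes 0.02, also below 0 with median centring. The 10 ciliated and secretory markers had -0.01, above 0 with median centring. The 11 leukocyte markers had 0.03, the 12 fibroblast and endothelial markers 0.01 and the 14 housekeeping genes -0.02.

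No gene was lower at 2-fold, and 7 genes had a mean log2 ratio of -0.5 or below, against 115 at 0.5 or above. With Agilent's own log ratio the folds of IFIT2, IFIT1, CXCL11 and IFNB1 were 57.7, 21.4, 13.3 and 8.85, and the series matrix also moved these 4 by over 1.5 times. Among the called genes the control signal of TNFAIP6, named after its value was seen, was not well above background, so it was at least 2.55-fold higher.

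After 24 h of RSV, 474 genes were higher and 645 lower by at least 2-fold on both arrays. The highest ratio was that of IL23A, the p19 subunit of interleukin-23, at 52.6-fold (5.72 ± 0.02). The matrix metalloproteinase genes MMP10 and MMP9 were 37.7-fold (5.24 ± 0.07) and 25.5-fold (4.67 ± 0.01) higher. MMP1 was saturated in the infected channel on both arrays and was at least 27.3-fold higher (4.77 ± 0.40). The antimicrobial beta-defensin gene DEFB103B was 27.4-fold higher (4.78 ± 0.03), FA2H, a fatty acid hydroxylase gene, 21.7-fold (4.44 ± 0.11) and BIRC3, encoding the apoptosis inhibitor cIAP2, 18.4-fold (4.20 ± 0.10). The lowest was FABP5, a fatty acid-binding protein of keratinocytes, at 18.5-fold lower (-4.21 ± 0.02). TYMS, encoding thymidylate synthase, was 9.04-fold lower (-3.18 ± 0.05).

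Among 56 interferon-stimulated genes, 14 were higher and 1 lower (median 0.48). ISG20, an RNA exonuclease gene, was 10.4-fold higher (3.38 ± 0.15), the ubiquitin-like modifier gene ISG15 9.20-fold (3.20 ± 0.02), IFIT1 8.22-fold (3.04 ± 0.03) and IFIT2 7.74-fold (2.95 ± 0.10). The lower one, named after its value was seen, was SP100 (-1.70 ± 0.04), a nuclear body protein gene whose second probe gave -0.13. Of 13 sensors and adaptors, 3 were higher (median 0.17): RIGI at 8.14-fold (3.03 ± 0.01), IFIH1 at 2.90-fold (1.54 ± 0.02) and the TLR3 adaptor gene TICAM1 at 3.13-fold (1.65 ± 0.02). The second probe of TICAM1 gave -0.05, and the mean over its probes (0.80) lost the call. TLR3 itself was uncalled (-0.21 ± 0.01). None of 15 interferon genes was called (0), but their median of 0.23 lay above 99.99% of random lists. Of these genes, 12 had positive and 1 negative ratios on both arrays, and IFNB1 was at -0.01. Of 16 interferon receptors and JAK-STAT regulators, 2 were higher (median 0.20), IFNGR2 at 2.70-fold (1.43 ± 0.05) and SOCS3 at 2.57-fold (1.36 ± 0.12). The second probe of SOCS3 gave 0.19, and the mean over its probes (0.78) lost the call. Of 20 antigen processing and presentation genes, 5 were higher (median 0.22), with the peptide transporter gene TAP1 at 2.42-fold (1.28 ± 0.03) and HLA-B at 2.40-fold (1.26 ± 0.04). Over the list, 14 had positive and 6 negative ratios on both arrays. The other called members, named after their values were seen, were the class I genes HLA-C, HLA-F and HLA-G. HLA-B shares much of its sequence with other class I genes, so the HLA values are uncertain and may not be separate results. Of the other HLA-B probes, 2 were not called (1.11 and 1.15), and HLA-B lost its call with median centring (0.95).

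Of 25 NF-kB targets, 12 were higher and 0 lower, and all 25 had positive ratios on both arrays (median 0.95). ICAM1, an adhesion molecule for leukocytes, was 9.07-fold higher (3.18 ± 0.05). Of 19 chemokines, 5 were higher and 1 lower (median 0.29), with CXCL8 at 12.2-fold (3.60 ± 0.03) and CXCL1 at 7.04-fold (2.82 ± 0.08) among the higher. The lower one, named after its value was seen, was CXCL14 (-2.22 ± 0.08). Of 24 cytokines and growth factors, 4 were higher (median 0.12), IL23A and CSF2, encoding GM-CSF, among them (CSF2 8.06-fold, 3.01 ± 0.25). Of 33 immediate-early genes, 10 were higher and 2 lower (median 0.39), with DUSP1 3.60-fold higher (1.85 ± 0.01). The lower ones were the transcription factor gene MYC (-3.32 ± 0.05) and AREG (-1.25 ± 0.04), the latter named after its value was seen. The second probe of MYC gave -0.30, and the mean over its probes was -1.81. Of 20 cell death genes, 3 were higher (median 0.40), PMAIP1 at 3.13-fold (1.64 ± 0.05) and the inflammatory caspase gene CASP4 at 2.76-fold (1.47 ± 0.02) among them.

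Of 11 heat shock proteins, 4 were higher (median 0.67), with HSPA1A at 11.5-fold (3.52 ± 0.20, mean over probes 2.87) and HSPA8 at 4.05-fold (2.02 ± 0.01). HSPA1A has a near-identical copy, and so has DEFB103B, so these values may belong to either copy. The histone genes below belong to a family of similar genes, so their values may not be theirs alone. Of 20 cholesterol synthesis genes, 5 were higher (median 0.68), with the sterol regulator gene INSIG1 at 3.79-fold (1.92 ± 0.04) and SC5D at 3.61-fold (1.85 ± 0.02). Of 16 epithelial junction genes, 6 were higher (median 0.54), with the claudin genes CLDN4 at 6.46-fold (2.69 ± 0.06) and CLDN7 at 3.42-fold (1.77 ± 0.06). The endoplasmic reticulum chaperone gene DNAJB9 was 2.95-fold higher (1.56 ± 0.13), the 1 called among 19 genes of the unfolded protein and integrated stress responses. Of these genes, 12 had positive and 7 negative ratios on both arrays, and the list median of 0.21 became -0.09 with median centring. Of 17 antioxidant genes, 2 were higher and 2 lower (median -0.23), the lower ones being AKR1B10 at 3.14-fold (-1.65 ± 0.03) and GCLC, the glutathione synthesis gene, at 2.96-fold (-1.57 ± 0.18, second probe -0.75). The higher ones, named after their values were seen, were HMOX1 (1.55 ± 0.05) and TXNRD1 (1.10 ± 0.02).

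Of 35 cell cycle genes, 27 were lower and 1 higher, with a median of -1.59 that was below those of all 10000 random lists. CENPF, a kinetochore protein gene, was 8.35-fold lower (-3.06 ± 0.02). The higher one, named after its value was seen, was CCNE1 (1.28 ± 0.02), encoding the G1 cyclin E1. The histone genes H4C3 and H4C13 were 11.4-fold (-3.51 ± 0.14) and 9.19-fold lower (-3.20 ± 0.13). Of 8 airway basal cell markers, 5 were lower and 1 higher (median -1.98), with the basal keratin genes KRT15 at 5.81-fold (-2.54 ± 0.03) and KRT14 at 5.17-fold lower (-2.37 ± 0.02). The higher one, named after its value was seen, was LAMB3 (1.22 ± 0.07), a laminin chain gene saturated in the infected channel on both arrays, so its value is a lower bound. In all, 3 of the 8 basal markers were positive on both arrays. Of 9 squamous differentiation genes, 5 were lower and 0 higher (median -1.23), with KRT16 at 8.40-fold (-3.07 ± 0.07) and KRT13 at 7.08-fold lower (-2.82 ± 0.15). The growth factor receptor gene FGFR3 was 9.54-fold lower (-3.25 ± 0.01), but its second probe gave -0.12 and the mean over its probes was -1.69.

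No member was called among 11 ciliated and secretory markers (0, median -0.03), 12 leukocyte markers (0, median 0.01, below 0 with median centring) or 12 fibroblast and endothelial markers (0, median -0.04, above 0 with median centring). The 14 housekeeping genes had a median of 0.04, and -0.22 with median centring. Other highest genes were the metalloprotease gene ADAM8 at 12.6-fold (3.66 ± 0.10), the anthrax toxin receptor gene ANTXR2 at 10.6-fold (3.41) and the lipolysis inhibitor gene G0S2, saturated in the infected channel on both arrays, at no less than 10.6-fold (3.41 ± 0.50).

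**Figure D2:**
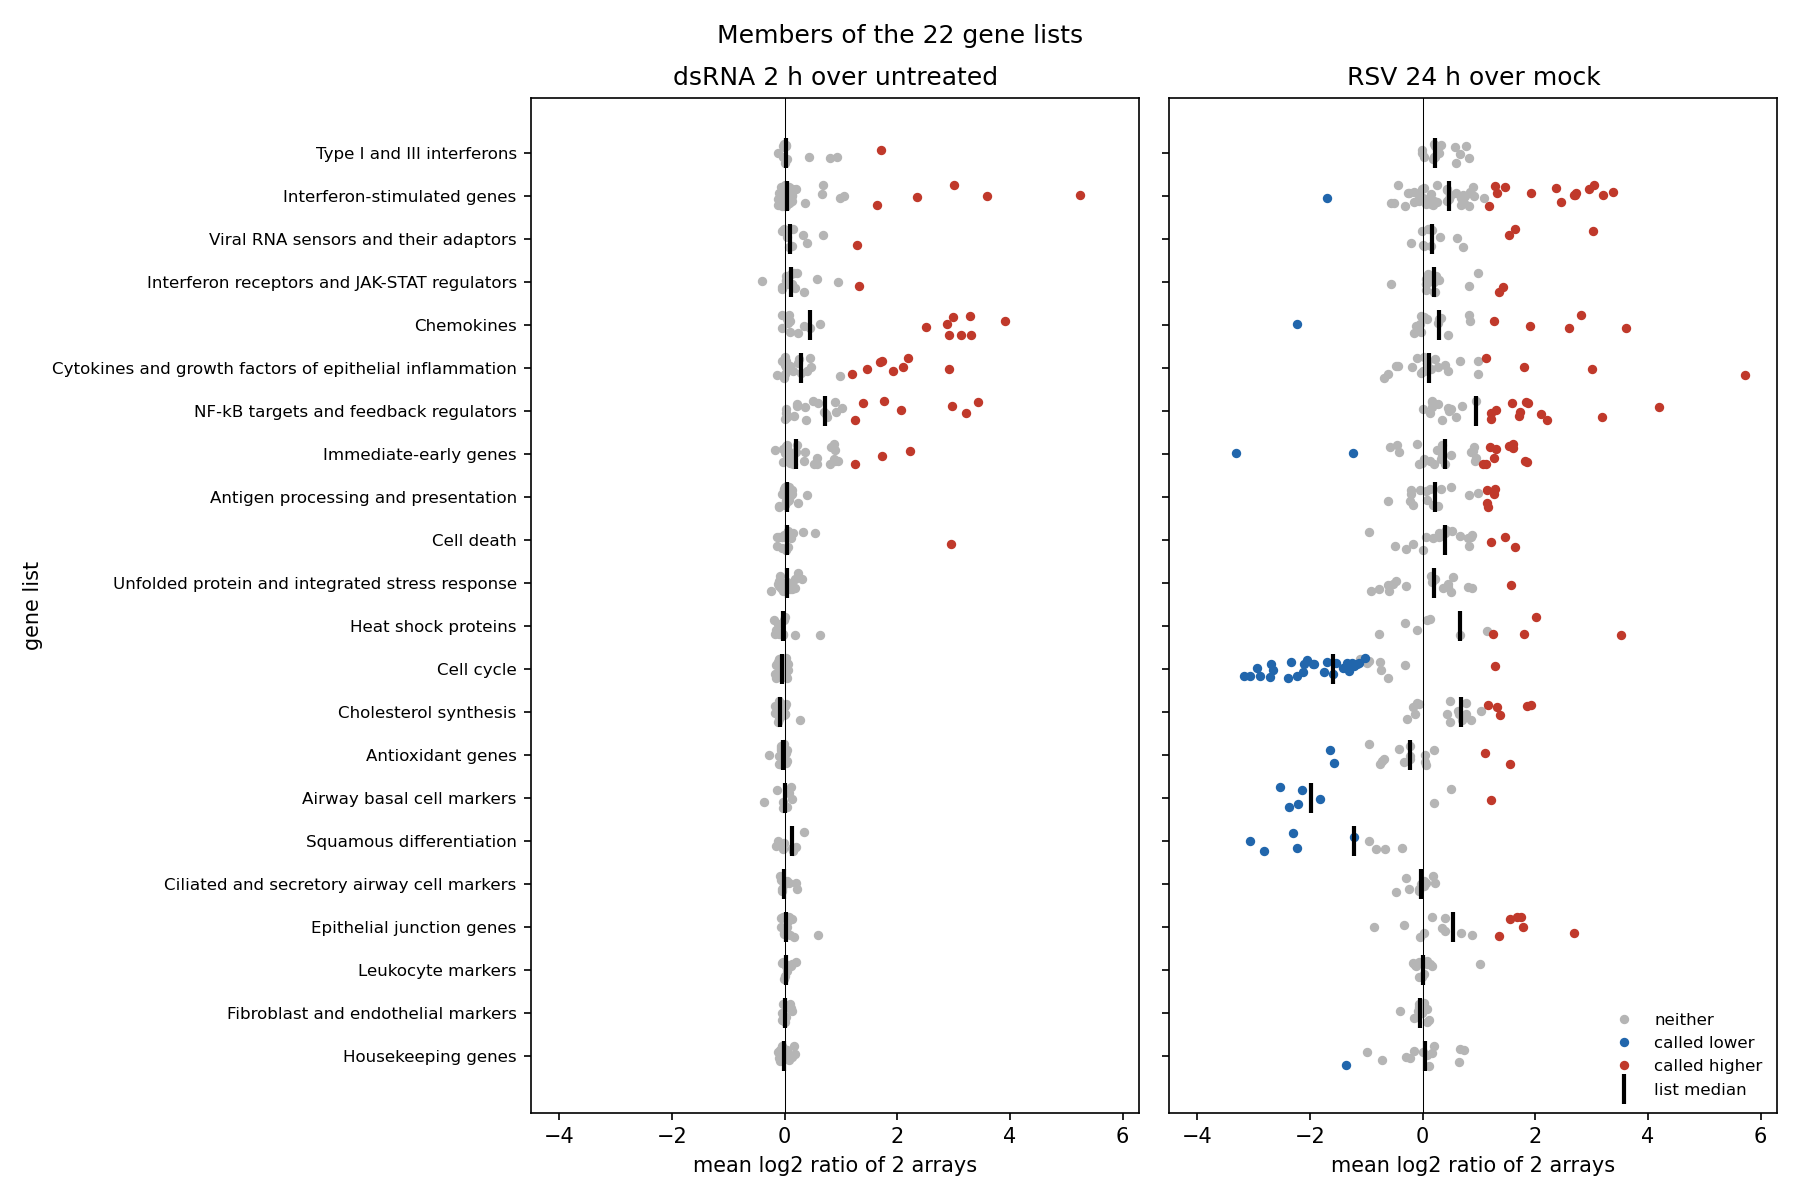
Mean log2 ratio of treated over control for the measured members of the 22 gene lists after dsRNA (left) and RSV (right), with red points for members called higher, blue for members called lower, grey for neither and a black bar at each list's median. Points are spread vertically at random within a list. The cell cycle list stands at a median of -1.59 after RSV and -0.05 after dsRNA, and the NF-kB list at 0.95 and 0.72.

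The split of 474 higher and 645 lower genes (42.4% higher) depended on the scaling: with median centring in place of loess it was 326 and 931 (25.9% higher). The median over all genes stayed within 0.1 of 0, as both scalings centre each array there. Agilent's own log ratio gave larger folds for CXCL11 (12.6 in place of 6.04) and ICAM1 (15.2), the series matrix gave log2 ratios of 6.32 for IL23A and 4.81 for BIRC3, and Agilent's ratio raised the list medians of the interferons to 0.72, interferon-stimulated genes to 0.81 and immediate-early genes to 0.87.

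Between the comparisons, 27 of the genes called higher were shared, out of 46 after dsRNA and 473 after RSV among 15511 genes measured in both. Independent lists of these sizes would share 1.40, and 10000 random lists matched on brightness shared 9 at most. No gene was called in opposite directions (0), which only the 46 genes higher after dsRNA could have been, so this says little. CXCL8 (15.1-fold after dsRNA, 12.2-fold after RSV), IFIT1, IFIT2, CXCL1, CXCL11 and ISG15 were the shared genes with the largest smaller ratio. Across all 15511 genes, which are not independent replicates, the mean log2 ratios had Pearson's r of 0.24 and Spearman's rho of 0.19. With median centring, which leaves trends of the ratios with brightness, r was 0.36.

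**Figure D3:**
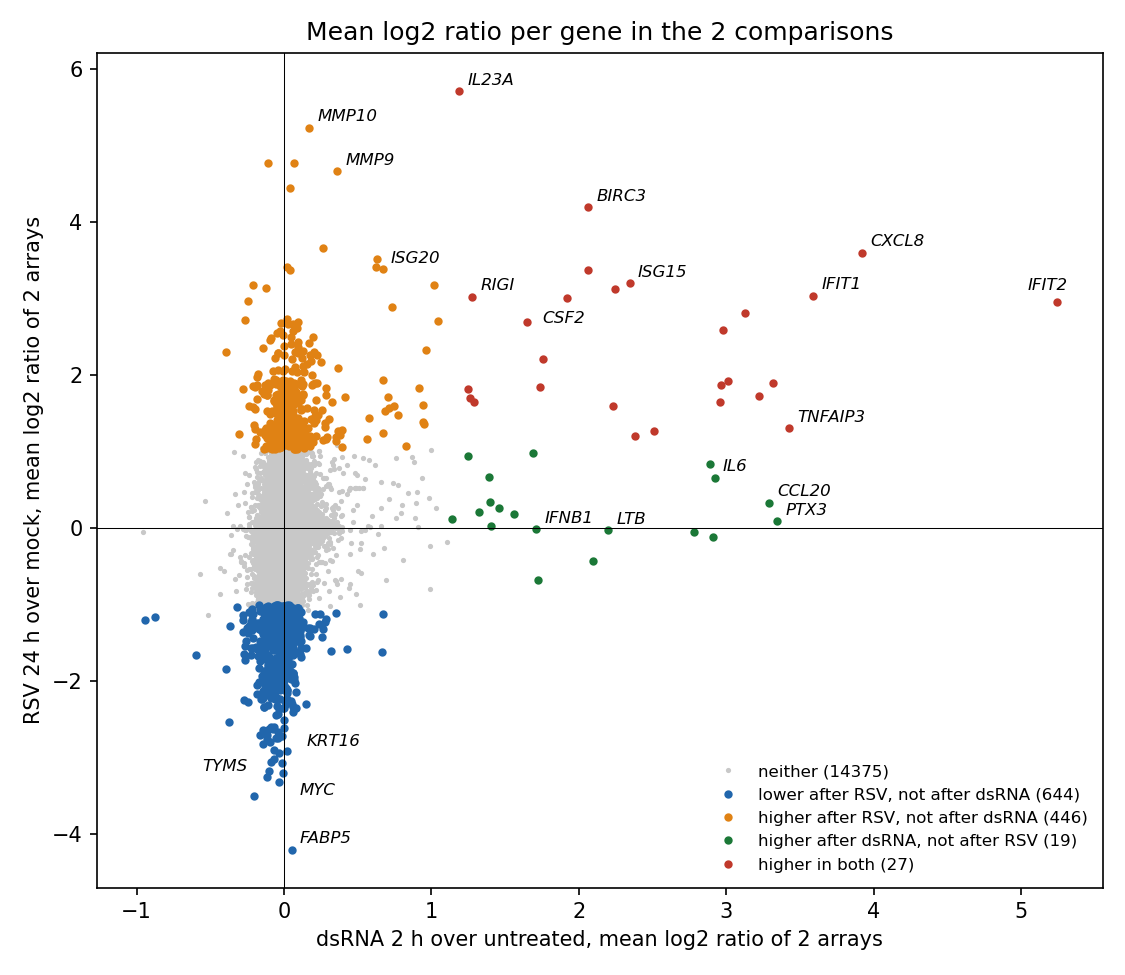
Mean log2 ratio of each gene after dsRNA (horizontal) and after RSV (vertical), coloured by call. The 27 shared genes lie in the upper right, 19 genes higher after dsRNA but not called after RSV lie closer to the horizontal axis, and the 644 genes lower after RSV lie close to 0 on the dsRNA axis.

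The other 19 genes called after dsRNA did not reach 2-fold on both arrays after RSV. PTX3 had 0.09 ± 0.02 after RSV, CCL20 0.33 ± 0.05, IL6 0.66 ± 0.03 and LTB -0.03 ± 0.01. Some came near the threshold: IL1A (0.99 ± 0.14), TNFAIP8 (0.95 ± 0.07) and CXCL10 (0.84 ± 0.03), named after their values were seen. Of the 19, 5 were below 0 on both RSV arrays. In the other direction MMP10, DEFB103B, MMP1, FA2H and MMP9 were uncalled after dsRNA, with 0.17 ± 0.09, -0.11 ± 0.03, 0.06 ± 0.08, 0.04 ± 0.14 and 0.36 ± 0.18. IL23A, called in both, was 2.28-fold higher after dsRNA (1.19 ± 0.16), and BIRC3 4.18-fold (2.06 ± 0.22). The lowest genes after RSV lay near 0 after dsRNA, with FABP5 at 0.05 ± 0.08, MYC by its brightest probe at -0.04 ± 0.01 and TYMS at -0.10 ± 0.28. These differences were not tested. Stimulus, exposure time, control and software version all change together between the comparisons, so their parts cannot be told apart.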

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

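All alternatives here were planned before the data were examined. Technical repeats give no test, so a value is described by its size. No named gene that was called changed sign under an alternative. Of 1382 alternative values of named genes, 1073 stayed within the spread of the pair and 309 moved beyond it. The 1073 are no measure of stability. Each array alone lies within that spread by construction, and a changed detection filter leaves a value as it is. The mean over probes and leaving out saturated spots can move only genes with several probes or saturated spots. Of 484 alternative list medians, 334 stayed within the spread, 148 moved beyond it and 2 turned sign, counting only lists whose reported median lay outside the central 95% of random lists. These were cell death (0.047, then -0.022) and squamous differentiation (0.13, then -0.031) after dsRNA with median centring. Counting every list, it turned 7 of 22 medians after dsRNA and 4 of 22 after RSV. Thresholds moved counts by construction. At 1.5-fold, 80 genes were higher and 3 lower after dsRNA, 1162 higher and 1622 lower after RSV, 48 higher and 2 lower genes were shared, and 16 genes followed the dye after dsRNA. At 3-fold, 171 were higher and 173 lower after RSV, and 0 followed the dye. Agilent's log ratio gave 697 higher and 988 lower genes after RSV, and the series matrix 717 and 952. Normexp with offset 0, which changes the offset alone, gave 647 and 937, against the reported 474 and 645. After dsRNA these settings gave 64, 62 and 63 higher genes, against 46. The offset used therefore lowered the reported counts, and setting it to 0 brought them near those of Agilent's log ratio and the matrix. What else separates these sources was not tested. Median centring leaves trends of the ratios with brightness on all 4 arrays. The correlation across genes was 0.36 with it and 0.22 with Agilent's log ratio, and the cause was not tested. With each array of a pair alone, it was 0.19 to 0.21, lower genes after dsRNA were 0 to 2 and shared lower genes 0 to 1; 58 to 69 genes were then higher after dsRNA, 533 to 544 higher and 708 to 792 lower after RSV, and 31 to 32 higher genes were shared. All other counts lay within 1.5 times the reported ones, leaving out saturated spots gave no value for MMP1 and G0S2 after RSV, and requiring Agilent's p under 0.01 removed no call (46, 474 and 645). No paired analysis was possible because each result comes from a size rule on 1 sample per group. Brightness limits the calls: in a split added later, simulated 3-fold changes were called for 100% of probes above the median brightness, and below it for 6 of 21 in the dsRNA pair and 4 of 20 in the RSV pair.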

Other observations

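The tests and genes in this part were all chosen after the results were seen. Families of genes sharing a symbol prefix and with at least 8 measured members were scanned, 282 after dsRNA and 287 after RSV. After dsRNA the 1 median below all 10000 random lists matched on brightness was that of zinc finger genes (ZNF), -0.031 over 356 genes, with 0 called, 101 negative and 24 positive on both arrays, and medians of -0.002 and -0.072 on array 1 and 2. The CXCL and IL prefixes lay above all (0.28 and 0.03). After RSV 4 lay below all (MCM, MRPL, POLR and ZNF) and 2 above (SEC and OR), with -0.085 for ZNF and 0.066 for OR. Of 49 genes of the large mitochondrial ribosome subunit (MRPL), 7 were called lower and 0 higher, with a median of -0.65 and negative ratios on both arrays for 44. Of 28 genes of the small subunit (MRPS), 7 were lower and 1 higher (MRPS6), with a median of -0.73 and negative ratios on both arrays for 26. RNA polymerase subunit genes (POLR) had 5 of 31 lower and a median of -0.55, nucleoporin genes (NUP) 6 of 20 and -0.41, and the MCM prefix 6 of 11 and -1.35. The 6 are the replicative helicase genes MCM2 to MCM7, all members of the cell cycle list too. The SEC prefix, many of whose members act in secretory transport, had 20 of 24 genes positive on both arrays, 2 called higher and a median of 0.58. The medians of MRPL, MRPS, POLR, NUP, MCM and SEC kept their sign under 5 other background and scaling settings. Among random lists their percentiles were 0.1 or below, and 100 for SEC.

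Several genes depend on which probe is read. TNF was uncalled after dsRNA by its brightest probe (0.40 ± 0.07), while its other probe gave 2.77 ± 0.04 after dsRNA and 1.45 ± 0.02 after RSV. CA12 had -1.35 ± 0.01 after RSV by its brightest probe and 1.99 ± 0.12 by the other, the 1 gene whose probes were called in opposite directions. After RSV, 76 of 115 called genes with several measured probes had a probe that was not called. C15orf39 was the 1 gene that followed the dye at 2-fold (1.22 and -1.25 on the RSV arrays). Of the 46 genes higher after dsRNA, 5 were below 0 on both RSV arrays: EDN1 (-0.44), IL1B (-0.68 ± 0.03), CX3CL1 (-0.12 ± 0.06), LTB and IFNB1.

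The first pattern is the lower level of cell cycle genes after RSV. A bias of these probes for 1 dye would give opposite signs on the 2 arrays. The 27 of 35 genes called lower had the same sign on both, which a call requires. The list median, -1.57 on the array nearer to 0, followed from these calls and is no separate check. Background correction or normalization would have to bring the list median toward 0, but under 5 other settings the median nearest to 0 was -1.50. A difference between the cultures other than infection cannot be told apart from it, because there is 1 infected sample and the treatment of the mock-infected cells is not described in full. Infection itself, the difference the design names, stays open and was not tested separately.

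The second pattern is the absence of genes called lower after 2 h of dsRNA. If the choice of background correction or normalization hid them, another setting should give lower genes, but the highest count over 5 other background and scaling settings was 0. The median over all genes lay near 0 under each of these settings, so a decrease shared by most genes would not be seen. Small decreases stay open, because the procedure itself misses most of them. Of simulated 2-fold lower probes, 5% were called, with a median estimate of -0.77, against 90% of 4-fold ones. A hypothesis left open is that 2 h is too short for existing transcripts to be lost. The series has no other dsRNA time, so this was not tested.

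The third pattern is the smaller share of higher calls after RSV when arrays are median-centred. Before loess, RSV ratios fell with brightness on both arrays, with a Spearman's rho across probes of -0.37 and -0.32. A dye curve that bends the same way on both arrays would give opposite signs, as it did in the dsRNA pair (0.78 and -0.89), so the value nearer to 0, -0.32, argues against it; curves of each array's own stay open. Additive signal in the infected channel would leave no trend among bright probes: within the brighter part the rho was -0.032 on one array and -0.14 on the other, which does not decide. An RNA-linked change of abundant transcripts with infection may also contribute and was not tested, so the balance of higher and lower genes after RSV stays open.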
